A study of Homo sapiens with 6 samples.

How the data were processed

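Total RNA from 6 cultures of HEK293 cells was labelled with Cy3 as cRNA and hybridised by the authors to one-colour Agilent arrays, 1 array per culture. Per the labels, the cultures were ATG7+/+ cells and ATG7-/- clones 1 and 2, each untreated and each after 72 h in 300 nM aphidicolin and 2 weeks without it. Per the file headers, the authors scanned the slide and extracted spot intensity with Agilent Feature Extraction 12.1.1.1 (protocol GE1_1200_Jun14, grid build hg19). The deposited scanner tables hold, for each of 62976 spots, a background-subtracted and spatially detrended intensity (the processed signal) and the median pixel intensity of the spot and of its local background, without normalization between arrays. All 6 arrays lay on 1 slide and shared 1 scan. The 2 arrays of treated clones lay in row 2 of the slide and the other 4 in row 1.

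The deposited series matrix equalled the processed signal of the scanner tables, with ratios between 0.995 and 1.005, as linear intensity rounded to 3 digits and not centred. Its column medians were 6.13 (ATG7+/+ untreated), 5.3 and 5.08 (clones 1 and 2 untreated), 7.74 (ATG7+/+ after aphidicolin), 6.44 and 5.79 (clones 1 and 2 after aphidicolin). How the authors normalised these values for their own comparisons is not given in the sources used here, and neither is the position of the ATG7 edit. Of the 60901 non-control spots, 53.9% were well above background in untreated ATG7+/+ cells and 51.8% and 51.2% in the untreated clones 1 and 2. After aphidicolin the share was 58.3% in ATG7+/+ cells and 54.2% and 53.3% in the clones. No spot was saturated, and 54 to 70 spots per array were marked as outliers. The 75th percentile of the processed intensity lay between 103.8 and 120.1.

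Expression values were log2 of the deposited processed intensity minus the 75th percentile of each array over the 58201 non-control probes. Spots of one probe were averaged on the log2 scale, outlier spots were left out, and 3 probes that lost an array in this way were dropped. Of 58201 probes, 31104 were matched to 1 current gene symbol through their RefSeq accession in a RefSeq gene table, 27097 were left unnamed, and 0 matched several symbols. The gene table follows a later genome build than the grid of the array, so it served for names, chromosomes, gene order and gene length, and no coordinates are given. Of 22439 named genes, 16744 had a probe well above background on at least 2 of 6 arrays and were tested, each by the probe with the highest mean over the 6 arrays. A probe counted as above background on an array where most of its spots did.

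Genes were tested with limma 3.58.1 in R 4.3.3. The means of the 4 groups were fitted to the 6 arrays, which left 2 residual degrees of freedom, both from clone 1 against clone 2. The single ATG7+/+ arrays are therefore assumed to vary as the clones do. eBayes gave 2.38 prior degrees of freedom and a prior SD of 0.188 (log2). Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the 16744 genes, with a threshold of 0.05. The comparisons were aphidicolin in ATG7-/- cells (2 against 2 arrays), ATG7-/- against ATG7+/+ untreated and after aphidicolin (2 against 1), aphidicolin in ATG7+/+ cells (1 against 1), the difference between both responses, and aphidicolin over the 3 lines with genotype in the model (3 residual degrees of freedom). In comparisons of 2 groups, where one group had no array above background, the fold is given as a lower bound from the lowest signal well above background on each array, and a fitted log2 difference beside it is not a bound.

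36 gene lists (1261 entries) were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. One list had no gene on the array. Members were also counted after adjustment over the list alone. For ATG7+/+ cells after aphidicolin, the list median is also given as a percentile among 10000 random lists of the same size and matched signal, as a description of 2 arrays. The same percentiles for the other comparisons were added after the values were seen, from separate random draws. Lists, comparisons, alternatives and the rule for naming genes were chosen before the data were examined. ATG7 comes first. In each comparison the rule then names, among called genes above background on every array of the higher group and with one sign in every pair of arrays, the 10 largest in each direction (5 for the comparisons after aphidicolin, in ATG7+/+ cells and over the 3 lines). Uncalled genes with the smallest p fill up to 5 places and are given as values. Up to 4 members of each list, 6 tumour suppressor genes and SQSTM1 were added. Symbols starting with LOC or LINC were left out, as were clone names. 5 of these genes and 1 list are not reported here, and the counts of named genes, of list results and of called lists leave them out.

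The clone numbers stand for the same lines before and after the drug. The difference between clone 1 and clone 2 correlated across genes between untreated and treated arrays with r = 0.433, so they pair the samples, and the line was tried as a block. For the genotype comparisons the line entered as a random block, whose correlation (0.0517) was estimated from a model of genotype and treatment, since the 4 group means left too few residuals. Alternatives were normexp background correction (offset 50) on the median spot intensity, which took the place of the mean spot intensity because the latter is not among the columns used here, quantile normalization, median centring, the deposited matrix values, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, every probe tested separately, eBayes with trend and robust, a 2-fold minimum, an adjusted p under 0.1, each ATG7-/- array left out in turn, each line left out, the ATG7-/- arrays alone and treatment without genotype. A slide block could not be fitted because there was 1 slide. Leaving out the ATG7+/+ array after aphidicolin was added after the values were seen.

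The pipeline was tested on simulated data with the spread of these arrays, in which 200 of 16744 genes were changed, with genes drawn independently of each other. Of genes changed 4-fold, 91.0% were recovered for aphidicolin in ATG7-/- cells, 68.7% for the genotypes untreated, 79.1% for the genotypes after aphidicolin, 52.2% for ATG7+/+ cells, 7.46% for the difference of responses and 97.0% over the 3 lines. Of genes changed 2-fold, 5.97%, 0%, 1.49%, 0%, 0% and 64.2% were recovered. Between 2 and 15 unchanged genes were called. In the real data 1043 genes were called between genotypes untreated and 815 after aphidicolin, which makes the adjustment less strict than with 200 changed genes. The simulated shares therefore do not give the sensitivity of these 2 comparisons. The single ATG7+/+ arrays were simulated with the spread of the clones, so that assumption was not tested. A list shifted by a log2 value of -0.5 was found at the preset correlation (adjusted p = 1.2e-21, 0 other lists called) and missed with an estimated correlation (adjusted p = 0.268). Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots, and statmod 1.5.0 served limma. Probes without a name, control probes and differences between the clones were left out of the comparisons and are described separately.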

Results

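Gene expression was measured in HEK293 cells, a line of human embryonic kidney origin, of the ATG7+/+ and ATG7-/- genotypes. ATG7 encodes an enzyme that autophagy needs to attach LC3 to membranes. 3 lines were compared, namely the ATG7+/+ cells and 2 ATG7-/- clones (clone 1 and clone 2). Each line was measured once untreated and once after 72 h in 300 nM aphidicolin, an inhibitor of replicative DNA polymerases, followed by 2 weeks without the drug. This gave 6 one-colour Agilent arrays, in groups of 1 (ATG7+/+) and 2 (ATG7-/-) per treatment. Between 51.2% and 58.3% of the 60901 non-control spots were well above background on an array, and 16744 genes were tested. The 2 ATG7-/- arrays of a treatment came from different clones, and no line was measured in a repeat culture, so the errors given here describe the spread between clones. The number of arrays limits the precision throughout.

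ATG7 itself was read by 2 probes. Probe A_23_P143987, the brighter, gave log2 signals (relative to the 75th percentile of the array) of 0.93 in untreated ATG7+/+ cells, 0.69 and 0.83 in the untreated clones 1 and 2, 0.94 in ATG7+/+ cells after aphidicolin, and -0.19 and 0.78 in clones 1 and 2 after aphidicolin. Probe A_24_P944827 gave -0.63, 0.02, -0.57, -0.37, -0.21 and -0.45 in the same order. The difference between ATG7-/- and ATG7+/+ cells was -0.17 (SE 0.44, adjusted p = 0.827) untreated and -0.65 (adjusted p = 0.425) after aphidicolin. Where the probes lie relative to the edit is not given in the sources used here, so these values do not check the genotype.

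The response of ATG7-/- cells to aphidicolin addressed what replication stress leaves behind in cells labelled as lacking ATG7, with tumour suppressor genes as the group of interest. The 32 genes of amino acid supply and the integrated stress response, which cells switch on when amino acids run short, were all lower 2 weeks after the drug, with a median log2 change of -0.62 and a mean of -0.67 (2 arrays against 2). Their median was -0.66 without the 1 gene above background in neither group. CHAC1 had a change of -1.93 (SE 0.31), CTH -1.23 (SE 0.18), SLC7A11 -0.85 (SE 0.15) and GPT2 -0.73 (SE 0.15), each with an adjusted p of 0.941. No gene of the list passed over all genes tested, and 11 were lower when adjusted over the list alone. The list was called lower with camera at its preset correlation (adjusted p = 7.56e-26) and not with an estimated correlation (adjusted p = 0.934). The estimated setting also missed a simulated shift of -0.5 in this list (camera, adjusted p = 0.268), so a call lost with it decides nothing either way.

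Tumour suppressor genes showed no change in ATG7-/- cells after aphidicolin that passed the test. 0 of the 93 genes tested passed in limma, over all genes and adjusted over the list alone, and 0 had an unadjusted p under 0.05. Their median log2 change was 0.00 and their mean 0.04, beside a median of 0.04 for all genes. The list test, which sets the list against all other genes, leaned down and was not called (adjusted p = 0.829, and 0.978 with an estimated correlation). RB1 had a log2 change of 0.18 (SE 0.19), CDKN2A -0.07, BRCA1 -0.04 and BRCA2 -0.21. The list median was -0.04 without the untreated clone 1 array and 0.08 without the untreated clone 2 array.

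**Figure D1:**
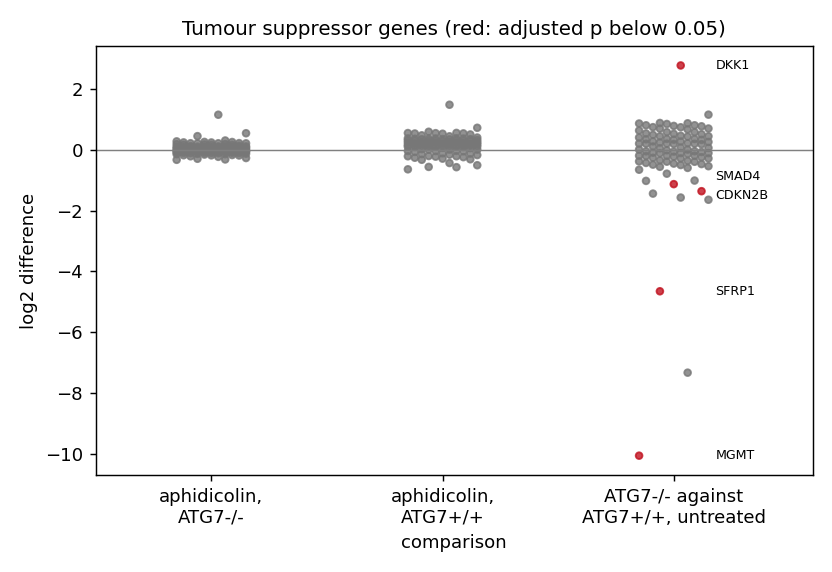
Log2 differences of the 93 tumour suppressor genes (1 point per gene) after aphidicolin in ATG7-/- cells (2 arrays against 2) and ATG7+/+ cells (1 against 1), and between untreated ATG7-/- and ATG7+/+ cells (2 against 1). 0 genes passed after aphidicolin, and 5 (DKK1, MGMT, SFRP1, CDKN2B and SMAD4) passed between genotypes.

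No single gene passed in the response of ATG7-/- cells. limma called 0 genes of 16744, and 815 had an unadjusted p under 0.05 (559 higher, 256 lower). The smallest adjusted p was 0.496. The genes with the smallest p among those with a higher value were BEAN1-AS1 at 2.73 (SE 0.17, at least 1.78-fold), FGFBP1 at 2.70 (SE 0.21, at least 1.81-fold), TEKTL1 (at least 1.72-fold), TCERG1L (at least 1.51-fold) and DNAH9 (at least 1.66-fold). In the clones, all 5 were above background only after the drug. Dim control probes that match no human gene also read higher on the treated arrays, by a median log2 of 0.44 in clone 1 and 0.60 in clone 2. How far this accounts for the 5 genes, or for the excess of higher values, was not tested. Among genes with a lower value, SCARNA13 had -0.81 (SE 0.14) and FAM86JP -0.78 (SE 0.14), besides CTH, CHAC1 and SLC7A11.

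4 further lists were called in the response of ATG7-/- cells at the preset correlation, none with an estimated correlation (adjusted p = 0.934), and none had a member past the test over all genes or adjusted over the list alone. The 36 glycolysis and hypoxia genes had a median of -0.14 (24 negative, adjusted p = 0.0183), the 40 oxidative phosphorylation genes -0.08 (32 negative, adjusted p = 0.0215) and the 54 genes of ATR, CHK1 and fork repair -0.04 (36 negative, adjusted p = 0.0438). The 24 cytosolic heat shock genes had a median of 0.24 (18 positive, adjusted p = 0.0275), with HSPA1B at 1.25 (SE 0.26, adjusted p = 0.941). When arrays were centred on their median, the list had -0.11, beside -0.31 for all genes. Centring on the median in place of the 75th percentile moved every gene by -0.35 in this comparison, by 0.24 and 0.21 between genotypes before and after the drug, by -0.31 in ATG7+/+ cells, by -0.33 over the 3 lines and by -0.03 in the difference of responses. All list medians are therefore read beside the median of all genes. Leaving out 1 array ended each of these 4 calls. Without the untreated clone 2 array the median was -0.06 for glycolysis (adjusted p = 0.18), -0.04 for oxidative phosphorylation (0.23) and -0.01 for fork repair (0.47), and without the treated clone 1 array -0.03 (0.10), -0.01 (0.60) and -0.03 (0.16). Fork repair also had -0.09 (0.11) without the treated clone 2 array. Heat shock genes had a median of -0.02 (adjusted p = 0.54) without the untreated clone 1 array and of 0.23 (adjusted p = 0.35) without the treated clone 2 array. Quantile normalization ended 3 calls with medians close to those above, at -0.13 for glycolysis (adjusted p = 0.056), -0.08 for oxidative phosphorylation (0.089) and -0.05 for fork repair (0.16). Among 10000 random lists of matched signal, fork repair lay at percentile 3.44, within the central 95%.

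Other lists bearing on the question were not called in ATG7-/- cells, with 0 members past the test in each, over all genes and adjusted over the list alone. The 32 genes of the core autophagy machinery had a median of -0.00 and a mean of 0.01 (camera down, adjusted p = 0.699), and the 17 selective autophagy receptors -0.04 (adjusted p = 0.46), with SQSTM1 at 0.39 (SE 0.21). The 42 genes at common fragile sites had a median of 0.05 (camera down, adjusted p = 0.699), so that the signs of median and test differed. This median was -0.02 without the treated clone 1 array and -0.03 without the treated clone 2 array. The 26 neuronal genes had 0.31 (adjusted p = 0.0516), and 0.28 with genes at or under background bounded or left out.

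The comparison of untreated ATG7-/- with untreated ATG7+/+ cells asked what separates the genotypes before any drug. Genes present at high level in one genotype were near background in the other. SOX11 was at least 964-fold lower in ATG7-/- cells (log2 difference -11.82, SE 0.18), with a log2 signal of 5.79 in ATG7+/+ cells and -6.03 ± 0.10 (SD, n = 2) in the clones. OCIAD2 was at least 676-fold, PEG10 at least 816-fold, SLFN11 at least 373-fold and MGMT at least 255-fold lower, each with an adjusted p of 0.000822. CTSF was at least 315-fold higher (log2 difference 10.46, SE 0.31, adjusted p = 0.00137), ZNF22 at least 268-fold, CRYGD at least 149-fold and PHYHD1 at least 120-fold higher. 605 genes were higher and 438 lower, every one at least 2-fold by the fitted value. Without the untreated clone 1 array 39 were higher and 59 lower, and without the untreated clone 2 array 40 and 61, of which 97 and 100 genes were shared with the full set.

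**Figure D2:**
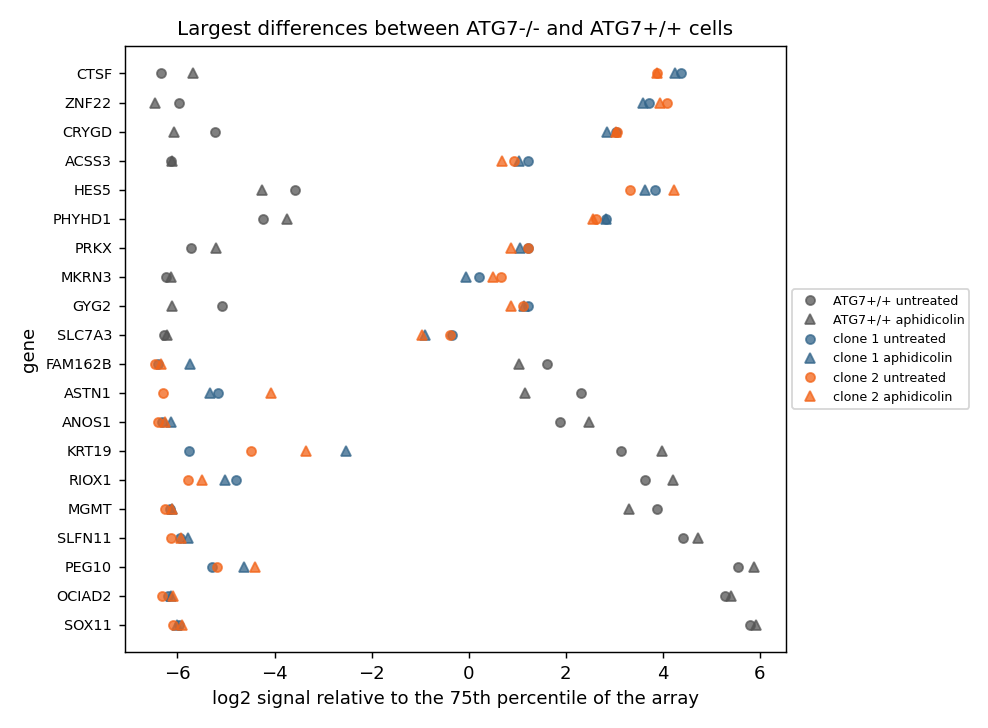
Log2 signal (horizontal axis, relative to the 75th percentile of the array) of the 10 genes with the largest higher and the 10 with the largest lower values in untreated ATG7-/- cells. They were taken from genes that passed the test, without symbols starting with LOC. Each point is 1 of the 6 arrays. For SOX11 both ATG7+/+ arrays lie far from the 4 ATG7-/- arrays, with 5.79 against -6.03 ± 0.10 (SD, n = 2) untreated.

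The other genes among the 10 largest in each direction that passed the test and the naming rule were ACSS3 (at least 38.2-fold), HES5 (log2 difference 7.16), PRKX (at least 42.1-fold), MKRN3 (at least 24.6-fold), GYG2 (at least 40.4-fold; log2 difference 2.48 by its second probe) and SLC7A3 (at least 13.9-fold) among the higher genes. The lower genes were RIOX1 (at least 216-fold), KRT19 (at least 154-fold), ANOS1 (at least 64.2-fold), ASTN1 (at least 86.6-fold) and FAM162B (by a log2 of at least 5.73). Leaving out the untreated clone 1 array raised the adjusted p of HES5 to 0.0506, of KRT19 to 0.0634 and of ASTN1 to 0.075. Leaving out the untreated clone 2 array raised that of MKRN3 to 0.0529, of KRT19 to 0.0523 and of ASTN1 to 0.0897. The fitted log2 differences were 6.89 for HES5, -7.63 for KRT19 and -8.62 for ASTN1 without the untreated clone 1 array. They were 6.46 for MKRN3, -8.91 for KRT19 and -7.48 for ASTN1 without the untreated clone 2 array. The fit assumes that the single ATG7+/+ array varies as the clones do.

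Tumour suppressor genes contained some of these differences. MGMT, which encodes the protein that repairs alkylated guanine, had a log2 difference of -10.07 (SE 0.18), with 3.87 in ATG7+/+ cells and -6.20 ± 0.07 (SD, n = 2) in the clones. SFRP1 was at least 17.5-fold lower (log2 difference -4.65, adjusted p = 0.00722), CDKN2B had -1.36 (adjusted p = 0.0449), SMAD4 -1.12 (adjusted p = 0.0466), and DKK1 was at least 6.90-fold higher (adjusted p = 0.0305). The median of the 93 genes was 0.06 and their mean -0.17, with 1 higher and 4 lower over all genes and adjusted over the list alone alike. The list was not called (camera down, adjusted p = 0.758; adjusted p = 0.900 with an estimated correlation), and its median was -0.01 after quantile normalization. RB1 had a log2 difference of 0.81 (SE 0.23, adjusted p = 0.111), BRCA2 0.75 (SE 0.24, adjusted p = 0.134), BRCA1 0.21 and CDKN2A 0.19. Of the 5 called genes, MGMT alone kept its call with each ATG7-/- array left out in turn. The highest adjusted p was 0.0786 for SFRP1, 0.143 for CDKN2B, 0.161 for SMAD4 and 0.108 for DKK1. CDKN2B also lost its call after normexp background correction (log2 difference -0.24), quantile normalization, median centring and eBayes with trend and robust (adjusted p = 0.0633), and DKK1 after normexp (0.51).

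Genes of autophagy and the lysosome differed between the genotypes in a few members. MAP1LC3A, a member of the LC3 family, was at least 16.3-fold lower in untreated ATG7-/- cells (log2 difference -4.55, adjusted p = 0.0141), ULK2 had -2.59 (adjusted p = 0.0228) and ATG3, whose product acts next to ATG7, 1.39 (adjusted p = 0.0463). The core autophagy list counted 1 higher and 2 lower of 32, and 1 and 3 adjusted over the list alone. Its median was 0.04, its mean -0.18 and its test down (adjusted p = 0.653; adjusted p = 0.892 with an estimated correlation), and its median was -0.12 after quantile normalization. None of the 17 selective autophagy receptors passed over all genes or adjusted over the list alone (median 0.02, and -0.12 after quantile normalization; adjusted p = 0.661). SQSTM1 had 0.35 (adjusted p = 0.416). Besides CTSF, the lysosome list held ATP6V1A at 1.42 (adjusted p = 0.0315), with 2 higher of 31, 4 adjusted over the list alone, a median of 0.16 and an adjusted p of 0.539. Without 1 of the ATG7-/- arrays the adjusted p reached 0.0958 for MAP1LC3A, 0.107 for ULK2, 0.139 for ATG3 and 0.133 for ATP6V1A.

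8 lists were called between the untreated genotypes at the preset correlation and none with an estimated correlation (adjusted p = 0.892). Histone genes had a median of 0.80 and a mean of 0.44 (30 of 32 positive, adjusted p = 4.82e-05), with H2BC12 at 1.85, H2BC9 at 1.02 and H1-1 at -7.93 (adjusted p = 0.00122). Over all genes 2 histone genes were higher and 1 lower, and 23 and 2 when adjusted over the list alone. Ribosome biogenesis and MYC targets had 0.45 (30 of 34 positive, adjusted p = 0.00758), with MYC at 1.69 and GNL3 at 1.28 as the 2 higher genes, and 3 higher and 1 lower adjusted over the list alone. Epithelial genes had -0.58 and a mean of -1.04 (14 of 22 negative, adjusted p = 0.0129), or -0.60 with genes at or under background bounded or left out. RAB25 was higher in that list, and CLDN3 (at least 16.8-fold), KRT19, SPINT1 and EPCAM were lower, the same 1 and 4 adjusted over the list alone.

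Interferon stimulated genes had a median of -0.42 (23 of 30 negative, adjusted p = 0.0170), or -0.40 with genes at or under background bounded. MX1 (at least 7.95-fold), PARP14 (at least 3.76-fold) and ISG20 were lower, 3 over all genes and 3 adjusted over the list alone. Genes at common fragile sites had -0.30 (29 of 42 negative, adjusted p = 0.0176), with LPP at -1.61 and DMD at -1.38 lower, and 1 higher and 2 lower adjusted over the list alone. Proteasome subunits had 0.32 (33 of 38 positive, adjusted p = 0.0317), with PSMA5 higher over all genes and 0 adjusted over the list alone. Genes of MCM and origin licensing had 0.37 (20 of 25 positive, adjusted p = 0.0381), with GINS4 higher in both counts, and oxidative phosphorylation 0.26 (32 of 40 positive, adjusted p = 0.0461), with 0 in both. Quantile normalization ended the calls of interferon stimulated genes (median -0.40, adjusted p = 0.057), fragile sites (-0.24, 0.062), proteasome (0.14, 0.36), MCM (0.23, 0.26) and oxidative phosphorylation (0.06, 0.60). Without the untreated clone 2 array the median was 0.20 for proteasome (adjusted p = 0.21), 0.26 for MCM (0.12), 0.22 for oxidative phosphorylation (0.12) and 0.27 for ribosome biogenesis (0.068). Without either treated clone array, which leaves these medians as they are, the adjusted p was 0.051, 0.07 and 0.07 for the first 3.

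The genotype difference also followed the signal of a gene, with a median of -0.44 over 755 dim genes (log2 signal between -5 and -4) and 0.20 over 2881 bright genes (over 4). The list medians were therefore set among 10000 random lists of matched signal, after the values were seen. Histone genes lay at percentile 100, ribosome biogenesis at 99.6, epithelial genes at 0.06, interferon stimulated genes at 0.38 and fragile sites at 0.61. Genes of MCM (percentile 93.4), proteasome (93.9) and oxidative phosphorylation (82.2) were within the range of the random lists, whose middle value was 0.18 for each. Their positive medians are therefore not separated from the trend with signal.

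Over the lists, 60 members were called between the untreated genotypes, and 7 (among them CCL2, CTSF, H1-1, HAND1, MGMT and MX1) kept their call with each ATG7-/- array left out in turn. For the other 53, the highest adjusted p over the arrays left out lay between 0.0634 and 0.167. Quantile normalization also ended the calls of H2BC9, GNL3, PSMA5 and SNAP25, median centring those of PMAIP1, DMD, H2BC9 and PSMA5, and normexp those of PARP14 (log2 difference -0.37) and TNC (-0.44), with adjusted p values between 0.0504 and 0.0886. HAND1, a transcription factor, had a log2 difference of 3.93 (adjusted p = 0.00289), while CCL2 was at least 5.56-fold lower (log2 difference -4.52, adjusted p = 0.0021). The genes of chromosome 18 (241 genes) were lower as a group, with a median of -0.53 relative to all other genes, and those of chromosomes 3, 14 and 9 were higher by 0.40, 0.40 and 0.38. For chromosome 18 the adjusted p was 2.8e-08 with camera at the preset correlation and 0.283 with an estimated correlation.

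After aphidicolin the same comparison of genotypes asked whether the differences persisted. Its means came from other arrays than those of the untreated cells, while the spread was estimated from the same clone arrays in both. SOX11 was at least 997-fold lower in ATG7-/- cells (log2 difference -11.87), OCIAD2 at least 698-fold, SLFN11 at least 435-fold and PEG10 at least 973-fold, each with an adjusted p of 0.000832, and RIOX1 at least 306-fold (log2 difference -9.48, SE 0.48, adjusted p = 0.00419). ZNF22 was at least 238-fold higher (log2 difference 10.22, SE 0.27, adjusted p = 0.00145), CTSF at least 291-fold, CRYGD at least 134-fold, HES5 at least 266-fold and GYG2 at least 35.1-fold (log2 difference 1.16 by its second probe). 522 genes were higher and 293 lower, again every one at least 2-fold by the fitted value. 381 of the higher and 253 of the lower genes were called in both comparisons, and 0 were called in opposite directions. The sign held for 600 of the 605 genes higher and 433 of the 438 genes lower in untreated cells. The arrays of both comparisons came from the same lines and shared each gene's estimate of spread, which favours calls in common. The treated clone arrays alone lay in row 2 of the slide, so that slide row coincides with genotype after aphidicolin. Without either untreated clone array 97 were higher and 85 lower, without the treated clone 1 array 258 and 190, and without the treated clone 2 array 216 and 205.

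MGMT was at least 163-fold lower and SFRP1 at least 16.3-fold lower in ATG7-/- cells after aphidicolin, CDKN2B had a log2 difference of -1.63 and DKK3 1.62 (adjusted p = 0.0460). These 1 higher and 3 lower tumour suppressor genes became 1 and 6 adjusted over the list alone, with a median of -0.03 and an adjusted p of 0.368. MAP1LC3A (at least 13.6-fold) and ULK2 (-2.16) were lower among 32 core autophagy genes, 3 adjusted over the list alone (median -0.15, adjusted p = 0.473). 3 lists were called at the preset correlation, none with an estimated correlation (adjusted p = 0.983). Stress-response genes, the list of amino acid supply, had a median of 0.46 (23 of 32 positive, adjusted p = 0.0178), with ALDH1L2 at 4.32 (SE 0.29, adjusted p = 0.00815) and CTH at 1.40 as the 2 higher genes, and 13 higher and 1 lower adjusted over the list alone. Histone genes had 0.46 (29 of 32 positive, adjusted p = 0.00437), with H2BC12 and H2BC14 higher and H1-1 and H2AC8 lower, and 5 and 2 adjusted over the list alone. Epithelial genes had -0.52 (16 of 22 negative, adjusted p = 0.038), with KRT19, EPCAM, CLDN3 and SPINT1 lower, 4 also adjusted over the list alone. The histone call ended without the treated clone 2 array (median 0.32, adjusted p = 0.15), and the epithelial call after quantile normalization (-0.55, 0.083), without the treated clone 1 array (-0.25, 0.081) and without either untreated clone array (-0.52, 0.054). Among random lists of matched signal, the medians lay at percentile 100 for stress-response and histone genes and 0.07 for epithelial genes. The stress-response median was already 0.31 between the untreated genotypes, where that list was not called. Of 42 called list members 12 kept their call with each ATG7-/- array left out, among them MGMT, H1-1, ALDH1L2, KRT19, CLDN3, HAND1 and MX1. The other 30 lost it, among them SFRP1 (highest adjusted p 0.0567), CDKN2B (0.0967), DKK3 (0.124), MAP1LC3A (0.0615), ULK2 (0.0845), CTH (0.135), EPCAM (0.0695), SPINT1 (0.0902), H2BC12 (0.0571), H2BC14 (0.156) and H2AC8 (0.0990). Quantile normalization also ended the calls of CTH (adjusted p = 0.061), H2AC8 (0.0523) and H2BC14 (0.0543), and the deposited matrix values that of CTH (0.0508).

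The aphidicolin response of ATG7+/+ cells served as the reference for cells with ATG7 and rested on 1 array against 1, with the spread taken from the clones. The same 32 stress-response genes were all lower, with a median of -0.69 and a mean of -0.90, under the lowest of 10000 random lists of matched signal (percentile 0). CHAC1 had a value of -2.40, CTH -1.10 and SLC7A11 -0.98. No list was called with an estimated correlation (adjusted p = 0.844), and no list member passed over all genes. At the preset correlation, higher lists were proteasome subunits at 0.41 (36 of 38 positive, adjusted p = 1.45e-05), ribosome biogenesis and MYC targets at 0.45 (33 of 34, adjusted p = 1.66e-05), cholesterol synthesis at 0.47 (22 of 25, adjusted p = 0.000768) and heat shock genes at 0.47 (22 of 24, adjusted p = 0.00559), each at percentile 100, beside a median of 0.10 for all genes. Mitosis genes were also called, with 0.28 (35 of 39 positive, percentile 99.3). Under median centring they had -0.04, beside -0.21 for all genes. The stress-response list had an adjusted p of 2.63e-20 at the preset correlation.

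Smaller medians were called for ribosomal proteins at -0.08 (36 of 46 negative, adjusted p = 0.0176), glycolysis at -0.13 (21 of 36 negative, adjusted p = 0.0241) and mesenchymal genes at -0.13 (19 of 28 negative, adjusted p = 0.0249). Quantile normalization ended the calls of ribosomal proteins (median -0.02, adjusted p = 0.69) and mesenchymal genes (-0.18, 0.0504). In each called list 0 genes passed over all genes and 0 adjusted over the list alone. With an estimated correlation the adjusted p was 0.872 for ribosomal proteins and 0.844 for the others. The 93 tumour suppressor genes had a median of 0.18 (69 positive, adjusted p = 0.281, percentile 98.1), and 0 passed in either count. limma called 0 genes, with 1226 at an unadjusted p under 0.05 (712 higher, 514 lower) and a smallest adjusted p of 0.659. The genes with the smallest p on the lower side were FBP1 (at least 1.58-fold), LINGO3 (at least 3.02-fold), CASC9 (at least 1.37-fold), ALDH1L1 (-2.27) and OR2A2 (at least 1.35-fold). On the higher side they were CREB3L3 (at least 3.06-fold), UCN2 (at least 1.76-fold), WFIKKN2 (by a log2 of at least 0.58) and GJD3 (at least 2.67-fold; log2 change 0.41 by its second probe).

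The difference between the aphidicolin responses, ATG7-/- minus ATG7+/+, tested whether the clones responded otherwise than the ATG7+/+ culture. With 1 ATG7+/+ culture and no line with ATG7 restored, it cannot tie a difference to ATG7. Across genes, the response of clone 1 correlated more with that of ATG7+/+ cells (r = 0.365) than with that of clone 2 (0.168). A list difference from ATG7+/+ cells therefore need not hold alike in both clones. 9 lists were called at the preset correlation and none with an estimated correlation (adjusted p = 0.728). Proteasome subunits had a median difference of -0.33 (37 of 38 negative, adjusted p = 0.000103), from medians of 0.41 in ATG7+/+ and 0.04 in ATG7-/- cells. Ribosome biogenesis and MYC targets had -0.36 (33 of 34 negative, adjusted p = 0.000226), histone genes -0.35 (28 of 32, adjusted p = 0.00366), mitosis genes -0.24 (32 of 39, adjusted p = 0.00366) and cholesterol synthesis -0.33 (22 of 25, adjusted p = 0.00674), beside a median of -0.05 for all genes. Oxidative phosphorylation had -0.19 (34 of 40 negative, adjusted p = 0.0231) and DNA polymerases and S phase -0.19 (26 of 34, adjusted p = 0.0239). Positive differences were 0.35 for blood and immune cell genes (7 of 9, adjusted p = 0.0192) and 0.14 for stress-response genes (23 of 32, adjusted p = 0.0269). 0 members passed over all genes, and 1 blood and immune cell gene adjusted over the list alone. Among 10000 random lists of matched signal, the medians of oxidative phosphorylation (percentile 3.04), S phase (4.60) and blood genes (95.8) were within the central 95% and those of the other 6 were not. Between genotypes, the median was 0.32 untreated and -0.00 after aphidicolin for proteasome subunits, and 0.45 and 0.17 for ribosome biogenesis. It was 0.41 and -0.03 for cholesterol synthesis, 0.10 and -0.17 for mitosis, and 0.80 and 0.46 for histone genes. The untreated genotype comparison, the ATG7+/+ response and this difference all use the single untreated ATG7+/+ array, so they are not independent results.

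**Figure D3:**
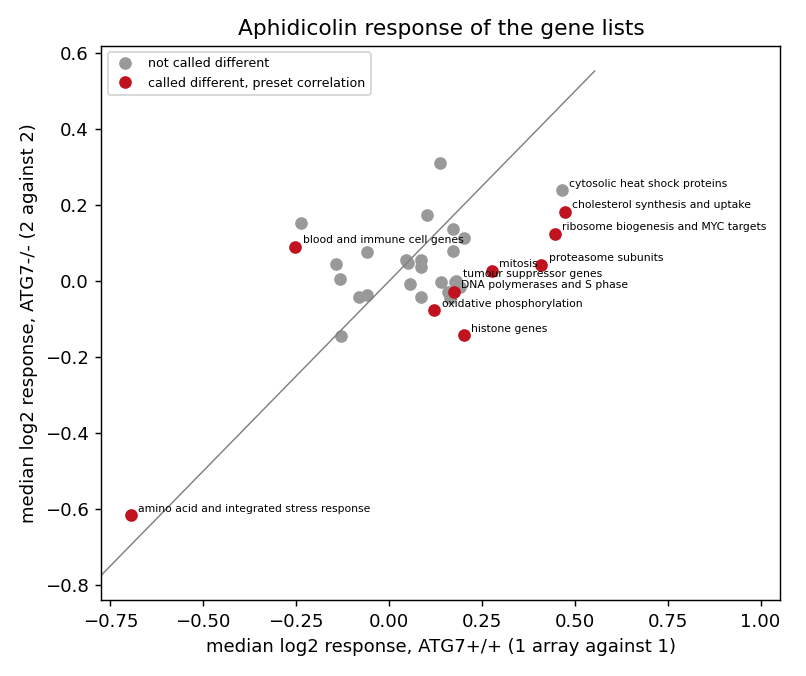
Median log2 response to aphidicolin of each gene list in ATG7+/+ cells (horizontal axis, 1 array against 1) and ATG7-/- cells (vertical axis, 2 against 2), at the 75th percentile scaling; red points are lists called different between the responses at the preset correlation, and the line marks equal responses. Stress-response genes lie at -0.69 and -0.62.

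Proteasome subunits kept this call under normexp (-0.33), quantile normalization (-0.19) and each ATG7-/- array left out. Ribosome biogenesis lost it without the untreated clone 2 array (-0.19, adjusted p = 0.082). Quantile normalization ended the calls of mitosis (-0.11) and histone genes (-0.20, adjusted p = 0.051 each), S phase (-0.06, 0.24), oxidative phosphorylation (-0.07, 0.36) and blood genes (0.30, 0.076). normexp ended those of stress-response genes (0.04, adjusted p = 0.14) and blood genes (0.15, adjusted p = 0.069). Without the untreated clone 2 array the median was -0.16 for cholesterol synthesis and -0.12 for mitosis (adjusted p = 0.12 each), -0.14 for S phase and -0.12 for oxidative phosphorylation (0.11 each) and 0.09 for stress-response genes (0.42). Without the treated clone 1 array it was -0.30 for cholesterol synthesis, -0.23 for mitosis and 0.17 for stress-response genes (0.061 each), -0.20 for histone genes (0.094), -0.17 for S phase (0.098) and -0.10 for oxidative phosphorylation (0.26). Without the treated clone 2 array it was -0.23 for S phase (0.077), 0.15 for stress-response genes and 0.21 for blood genes (0.14 each), and without the untreated clone 1 array 0.31 for blood genes (0.051).

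The 93 tumour suppressor genes had a median difference between responses of -0.15 (68 negative, adjusted p = 0.165; adjusted p = 0.728 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. limma called 0 genes for the difference, and 612 had an unadjusted p under 0.05. The smallest adjusted p was 0.999. Values with the smallest p were 2.31 for LINGO3, 2.44 for CASC9, 2.13 for ATE1OSP, 1.92 for KIF25 and 1.94 for MYOM1, and -3.26 for KCNF1, -1.87 for CREB3L3, -2.41 for MARS2, -1.55 for PRTN3 and -1.67 for GJD3, whose second probe had 0.02. All but ATE1OSP and KIF25 had at least 1 array without signal above background, so the size of these fitted values is not established. Each difference leans on the single ATG7+/+ pair of arrays and coincides with slide row, as the treated clone arrays alone lay in row 2.

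Over the 3 lines together, stress-response genes again had the smallest p of the lists. All 32 were lower in each line, with medians of -0.69 in ATG7+/+ cells, -0.71 in clone 1 and -0.50 in clone 2, and -0.61 over the lines (adjusted p = 5.65e-31; adjusted p = 0.408 with an estimated correlation). 0 passed over all genes and 23 were lower adjusted over the list alone. CHAC1 had a log2 change of -2.09 (SE 0.25), CTH -1.18 (SE 0.13), SLC7A11 -0.89 (SE 0.12) and GPT2 -0.74 (SE 0.11), each with an adjusted p of 0.371 over 3 lines. This call kept its direction and its side of the threshold under normexp, quantile normalization and each ATG7-/- array left out.

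**Figure D4:**
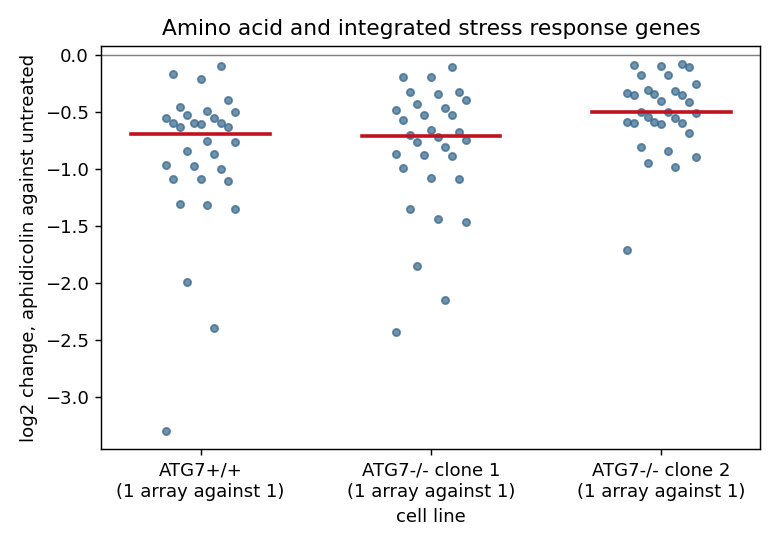
Log2 change after aphidicolin of the 32 amino acid and integrated stress response genes in each line (1 point per gene, 1 array against 1; red bars are medians). All 32 points lie under 0 in each line, with medians of -0.69, -0.71 and -0.50.

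6 other lists were called over the 3 lines at the preset correlation, none with an estimated correlation (adjusted p = 0.941). Glycolysis genes had a median of -0.07 (25 of 36 negative, adjusted p = 0.00295), with DDIT4 at -0.95 and STC2 at -0.70, and 3 lower adjusted over the list alone. DDIT4 and STC2 are also members of the stress-response list, so the 2 calls are not independent. Ribosomal proteins had -0.06 (41 of 46 negative, adjusted p = 0.00388). Ribosome biogenesis had 0.23 (29 of 34 positive, adjusted p = 0.00295), heat shock genes 0.32 (21 of 24, adjusted p = 0.00295), proteasome subunits 0.18 (35 of 38, adjusted p = 0.00472) and cholesterol synthesis 0.29 (23 of 25, adjusted p = 0.0091), beside 0.06 for all genes. Under median centring, which shifts every gene alike, these 4 had -0.10, -0.02, -0.15 and -0.05, beside -0.27 for all genes. HSPA1B had a change of 1.17 (SE 0.20), and 1 heat shock gene was higher adjusted over the list alone. No other member passed in either count. Without the untreated clone 1 array the median was 0.18 for ribosome biogenesis and 0.22 for cholesterol synthesis (adjusted p = 0.083 each), 0.17 for proteasome and -0.04 for ribosomal proteins (0.051 each). It was 0.30 for cholesterol synthesis without the treated clone 2 array (0.068) and -0.01 for ribosomal proteins without the treated clone 1 array (0.27), and quantile normalization gave -0.03 for ribosomal proteins (0.33).

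limma called 0 genes over the 3 lines, with 1767 at an unadjusted p under 0.05 (1082 higher, 685 lower). The smallest adjusted p, 0.0898, belonged to LINC02212, a gene chosen after its values were seen, with -3.17, -3.50 and -3.71 untreated and -5.75, -5.85 and -5.83 after the drug. Values with the smallest p on the higher side were 2.34 (SE 0.27) for FGFBP1, 1.24 for HTR4, 1.13 for VRTN, 0.82 for GZMH and 0.91 for DNAJB8, each without signal above background on at least 1 array, and RLN1 had -0.77. The tumour suppressor list had a median of 0.07 beside 0.06 for all genes (adjusted p = 0.813), with 0 of 93 past the test in either count.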

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

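Neighbouring-gene correlations and the splits of arrays were set as tests before their values were seen, and the other tests given here were chosen after the pattern was seen. 9 lists differed between the aphidicolin responses of ATG7-/- and ATG7+/+ cells by a test of the difference itself, with camera at the preset correlation and with none left at an estimated correlation. The median differences (ATG7-/- minus ATG7+/+, log2) were -0.33 for proteasome subunits, -0.36 for ribosome biogenesis and MYC targets, -0.35 for histone genes, -0.24 for mitosis, -0.33 for cholesterol synthesis, -0.19 for oxidative phosphorylation, -0.19 for DNA polymerases and S phase, 0.35 for blood and immune cell genes and 0.14 for stress-response genes. Under quantile normalization the median was -0.06 for S phase and -0.07 for oxidative phosphorylation, and under normexp 0.04 for stress-response genes. Each rests on 1 ATG7+/+ array per treatment, and the treated clone arrays alone lay in row 2 of the slide, so that slide row coincides with the difference of responses. The clones also differed in response, with r = 0.168 between them across genes, beside 0.365 between clone 1 and ATG7+/+ cells. The array of treated ATG7+/+ cells had the highest share of spots above background, 58.3%.

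Probes without a gene name, which no comparison used, also carried a signal between genotypes. Of 10058 tested, 35 were higher and 33 lower in untreated ATG7-/- cells, and 33 were higher and 19 lower after aphidicolin, at an adjusted p under 0.05 in limma. The other comparisons had 0.

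The genotype difference ran along chromosomes, with genes of chromosome 18 lower in both clones. The shifts of 23 chromosomes correlated with r = 0.913 across chromosomes between clone 1 untreated and clone 2 after aphidicolin, which share no array, so scaling or labelling of single arrays would not produce them. Genes 10 places apart were correlated at 0.076 in the lower of these differences (highest of 1000 shuffles 0.0227; 0.0374 with chromosome medians removed), against at most 0.0211 for aphidicolin (clone 2, highest shuffle 0.0208) and 0.0161 between the clones, which is consistent with a different chromosome content of the ATG7+/+ culture and the clones. Loss of ATG7 itself was not separable from this, as 21 of 23 chromosomes moved in the same direction in both clones. The arrays held 1 ATG7+/+ culture and no line with ATG7 restored.

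Stress-response genes were lower 2 weeks after aphidicolin in all 3 lines, as a list called at the preset correlation and not with an estimated correlation (adjusted p = 0.408), with 0 members past the test over all genes. Slide row would not explain the ATG7+/+ median of -0.69, from 2 arrays in row 1. These lay in columns 1 (untreated) and 4 (treated), so the place along the row was not separated from the drug. The median of -0.62 in the clones is confounded with row, since their treated arrays lie in row 2. Scaling and signal-dependent bias were tested with random lists of matched signal, and the list median closest to 0 (-0.50, clone 2) lay under the lowest of 10000 (-0.15). The state of the cultures at harvest could contribute and was not separable from the drug, as glycolysis and hypoxia genes had a median of -0.0686 over the lines. That list shares DDIT4 and STC2 with the stress-response list, so it is not a separate reading. The splits of 6 arrays into 3 and 3 number 10 and cannot give a share under 0.05. 1 split, the real one, had a list median this far from 0 (-0.61, highest other 0.51 in size). Among splits that parted the 2 arrays of every line, the highest other was 0.30 in size. All 10 called 0 genes (real 0, highest other 0). No split could call fewer than the real one, so this count decides nothing.

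Dim genes were higher after aphidicolin in each line, and so were control probes that match no human gene. Over 13 control probes of like signal, the lowest median difference among the lines was 0.445, with 13 of 13 higher in each line, which is consistent with a raised low end of the signal range on the treated arrays. Wider expression of weakly expressed genes may add to this, but the medians of 755 dim genes did not exceed those of the controls, with a lowest difference of -0.163 (bootstrap SD 0.105). Whether control RNA was added in equal amounts is not stated in the labels.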

How the results depend on the processing

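All alternatives were chosen before the data were examined, except leaving out the ATG7+/+ array after aphidicolin, which was added later. Of the counts of called genes between genotypes under an alternative, 40 stayed within 1.5 times their value and 26 moved. The other comparisons had 0 called genes, of which 139 counts stayed at 0 and 3 moved to 1. Results of a list or a named gene were counted once per alternative. Of list results, 305 kept their direction and their side of the threshold, 104 lost a call and 9 reversed. Of named-gene results, most of them not called, 1453 kept both, 119 lost a call, 74 gained one and 4 reversed. Of 70 calls of a named gene in a comparison, 32 held under each alternative run for single genes and 38 were lost under at least 1. These were the other scalings, the deposited matrix values, trend and robust, the block and arrays left out. Of 41 called list results, 0 held with an estimated correlation, 39 with normexp, 24 with quantile normalization and 41 with the deposited matrix values. The estimated correlation also missed a simulated list shift of -0.5, so calls lost with it decide nothing either way. The list of lower stress-response genes held in ATG7-/- cells, ATG7+/+ cells and over the 3 lines under each of these but the estimated correlation. Between untreated genotypes (605 higher, 438 lower), normexp gave 1136 and 703, eBayes with trend and robust 1760 and 919, and an adjusted p under 0.1 gave 1656 and 1129. Without a filter (22438 genes tested) 218 and 245 were called, and with all 6 arrays above background (14568 genes tested) 1028 were higher. After aphidicolin (522 and 293), normexp gave 510 lower, no filter 242 higher, trend and robust 1130 and 651, and an adjusted p under 0.1 gave 1027 and 670. Over the 3 lines, quantile normalization, median centring and an adjusted p under 0.1 called 1 lower gene each. The wider threshold and the genes tested follow from the alternative itself. For the others the cause was not tested. Leaving out arrays, with fewer samples, gave 39 to 605 higher and 59 to 438 lower genes untreated (the upper ends without the ATG7+/+ array after aphidicolin, which that comparison does not use), and 97 to 258 and 85 to 205 after aphidicolin. Of the called genes, 58.0% were higher untreated and 64.0% after aphidicolin, against 68.4% and 73.9% under median centring, and normexp gave 576 higher beside the 510 lower after aphidicolin. The line as a random replicate block gave 624 higher and 453 lower genes untreated and 538 and 299 after aphidicolin, and added the calls of COL5A1 (1.56), MAP2 (-3.34) and NEFL (-1.76) untreated. No call of a named gene was lost with a replicate block, nor one of the 30 called lists of the aphidicolin comparisons. The lists between genotypes were not run with it. Some values reversed. In ATG7-/- cells after aphidicolin, RB1 had -0.16 under median centring and core autophagy genes 0.00809 under normexp. Between untreated genotypes, ATG7 had 0.0694 under median centring, and under quantile normalization tumour suppressors had -0.00562, core autophagy -0.12 and autophagy receptors -0.12. The cause was not tested, except that median centring shifts every gene alike. With 1 array left out, the response in ATG7-/- cells (ATG7 -0.47, heat shock genes 0.24 and called with all arrays) ranged from -0.95 to 0.0145 for ATG7, -0.11 to 0.0376 for BRCA1, -0.0241 to 0.46 for heat shock genes, -0.0388 to 0.0777 for tumour suppressors, -0.15 to 0.0136 for autophagy receptors and -0.0317 to 0.0944 for fragile sites. A slide block was not run, since all arrays shared 1 slide. Signal over background limits the dim genes, as 51.2% to 58.3% of spots were well above it.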

Other observations

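All values in this part were chosen after the data were seen, except the correlations between lines and the gene-length values. The clones differed from each other at 26 genes over their untreated and treated arrays (13 higher and 13 lower in clone 2 at an adjusted p under 0.05 in limma, 1927 at an unadjusted p under 0.05). MAGEA2B (7.54), MAGEA12 (7.15), CSAG1 (6.69) and CSAG4 (5.38), cancer-testis genes, were higher in clone 2, as were CYTOR (4.21) and MIR4435-2HG (4.17). KLHDC9 (at least 123-fold), LXN (at least 116-fold) and MAP7D2 (at least 15.7-fold) were lower, with no clone 2 array above background. MAGEA12 was above background on 1 of 2 clone 1 arrays. HSPA1A read 8.18 and 9.08 in ATG7+/+ cells, -5.75 and -4.13 in clone 1 and -2.19 and -0.46 in clone 2, untreated and treated, with no clone 1 array above background.

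303 genes were above background on both ATG7+/+ arrays and on no ATG7-/- array, and 124 the reverse, while 208 genes were on in one clone and off in the other. A mean difference of at least 4-fold was seen for 720 genes between genotypes, 95 between clones and 7 between treatments. Among called genes with several probes between untreated genotypes, 225 of 239 had the same sign on all probes and 14 did not.

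The response to aphidicolin correlated across genes at r = 0.365 between clone 1 and ATG7+/+ cells, 0.168 between the clones and 0.137 between clone 2 and ATG7+/+ cells. Under normexp background correction these were 0.470, 0.290 and 0.0444 (Spearman -0.0156 for the last). Genes are not independent replicates. The length of a gene correlated with its response at a Spearman value of 0.00298 in clone 1, -0.155 in clone 2 and 0.00225 in ATG7+/+ cells. The 522 genes longer than 300 kb had medians of 0.03, -0.05 and -0.01, beside 0.05, -0.01 and 0.09 for the others.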
